A study of Mus musculus with 12 samples.

How the data were processed

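The samples were 6 kidneys of glyoxylate-injected mice, 3 WT and 3 cKO, each measured as an IP sample and a supernatant sample. Groups and replicate numbers were taken from the sample labels. The labels call the animals biological replicates. They do not say in which cells Mettl3 was deleted.

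Total RNA was immunoprecipitated with a polyclonal rabbit antibody against m6A, per the labels' protocols, and the eluted and unbound RNA were labelled as cRNA with Cy5 and Cy3. The deposited intensity values were made with Agilent Feature Extraction version 11.0.1.1, per the submitters' processing notes, as linear scanner intensities of both colours, and per the file headers these include background-subtracted signals and processed signals that are also dye-normalised. Each array had 62976 spots. No spot was saturated, and no 2 arrays held the same values. No dyes were swapped.

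From there, values were computed in R 4.3.3 with limma 3.58.1 and the data.table package (version 1.17.8). Control spots and spots marked as non-uniform or population outliers were left out, and spots of a probe were averaged on the log2 scale. The m6A ratio was log2 of red over green processed signal, centred on the median of each array, without loess, since many transcripts can shift one way in an enrichment experiment. The total signal was log2 of the sum of both channels, each first divided by its 75th percentile over non-control probes, and the single fractions were scaled in the same way. A probe was kept if it was well above background on at least 3 of 6 arrays, in both channels for the ratio, in either for the total signal and in its own for a fraction. For a probe with 10 spots, at least 0.5 of the spots had to be well above background. Genotypes were compared with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. IP was tested against supernatant as the ratio against 0, with a mean per genotype in 1 fit. Medians and widths per array were compared with exact permutation tests. A probe not well above background on any array of a genotype was compared per channel after normexp, loess and Aquantile. Values under the dimmest probe that was well above background on the array were raised to it. Where none was raised, the fold is a measured value, and it is open to dye bias.

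The 4 array comparisons were tested on simulated data with 100 probes changed 2-fold and 100 changed 4-fold. At a 2-fold change 9% were recovered for the m6A ratio, 29% for the total signal, 7% for the IP signal and 14% for the supernatant signal, and at a 4-fold change 89%, 99%, 97% and 91%. For IP against supernatant in WT the shares were 60% and 100%. Most 2-fold changes between genotypes would thus be missed. The simulated noise was independent and normal, with limma's variance of each probe and no slide effect. Recovery of genotype differences in the real data may therefore be lower, also for 4-fold changes. For IP against supernatant far more probes differed in the data, 19004 of 28363 in WT, which loosens the adjusted cutoff. The simulated shares for that comparison therefore do not carry over to the data.

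The files pair 50 probes, each with 10 spots, with an accession. Of these, 45 matched a symbol in a RefSeq gene table of assembly GRCm38.p6, used for names only, and 5 did not. The other probes have identifiers that were not matched to genes here. For this reason the planned looks at Mettl3, at other m6A writers, erasers and readers and at sex-linked genes were not run. The same holds for the tests of 37 gene lists, which were fixed before the data were examined and needed at least 5 measured members: 6 lists had a named probe, and the largest number was 4, in the list of fatty acid oxidation and peroxisome genes. Genes were named by a rule fixed before the data were examined. For the m6A ratio and the total signal it takes per direction up to 10 genes past the threshold with groups that do not overlap, and where fewer pass, those with the smallest p fill up to 5. It adds the 4 members of a described list with the smallest p, the 5 highest and 5 lowest ratios among genes called in both genotypes, of which only 4 were low, and reference transcripts. Unnamed probes are given by identifier, at most 2 that rose and 2 that fell.

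Alternatives fixed before the data were examined were normexp background correction with an offset of 50, the same normexp followed by loess and Aquantile, background-subtracted signals with values under 1 set to 1, other centring or scaling, other filters, trend and robust variance, an unadjusted threshold with a 1.5-fold change, the replicate number as a block, the slide as a block and leaving out each array. Normexp was planned on mean spot signals and was run on median spot signals, the ones used here. Added after the data were seen were fits within slide 2, the width of the ratio distribution, the spike-in reference with the strict filter, lowess of the ratio on mean signal with a span of 0.3, and adjustment over the named genes alone.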

Results

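Kidneys of 6 male C57BL/6 mice aged 6 to 8 weeks were profiled, 3 wild-type (WT) and 3 labelled as a conditional knockout of Mettl3 (cKO), the gene for the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on RNA. All 6 animals had received glyoxylate, a precursor of oxalate, by intraperitoneal injection at 100 mg/kg in 200 µl daily for 7 days, a model of calcium oxalate crystal deposition in the kidney. RNA from each kidney was split with an antibody against m6A into an immunoprecipitated fraction (IP, labelled with Cy5) and the supernatant (labelled with Cy3), and both fractions were hybridised to the same array, so that 12 samples lay on 6 arrays. The labels call the animals biological replicates, and the number of arrays, 3 per genotype, limits the precision of every value. Of 60706 probes, 52.1% to 56.1% were well above background in the IP channel. In the supernatant channel the share was 38.5%, 52.5% and 31.7% on WT arrays 1, 2 and 3 and 56.9%, 49.9% and 53.5% on cKO arrays 1, 2 and 3. WT arrays 1 and 3 shared slide 1, and WT array 2 lay on slide 2 with the 3 cKO arrays. No probe on the array was paired with the Mettl3 symbol here, so the genotype labels were not checked against the level of the targeted gene. Gene symbols could be given to 45 probes. Apart from control probes named for Gapdh and Pgk1, all other probes are known by their identifiers alone.

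The first question was which transcripts were recovered with the m6A antibody in each genotype. In WT kidneys the highest ratio among named genes was that of Rab5a, a small GTPase of early endosomes, with a log2 ratio of IP to supernatant of 3.18 ± 0.92 (SD, n = 3) relative to the median probe, and 2.95 ± 0.83 in cKO. Ppara, the nuclear receptor that controls fatty acid oxidation, followed at 2.91 ± 0.61 in WT and 2.32 ± 0.19 in cKO. Without 1 WT array the WT ratio ranged from 2.89 to 3.71 for Rab5a and from 2.56 to 3.11 for Ppara, so their order is not settled. Taf1a, a transcription factor subunit of RNA polymerase I, had 2.37 ± 0.25 and 2.17 ± 0.30, but was well above background in the supernatant on 1 of 3 WT arrays, and with normexp its ratios were 0.90 and 0.96. Uhrf1bp1l had 2.20 ± 0.92 and 1.93 ± 0.22. Dnajc11, a mitochondrial inner membrane organiser, had 1.61 ± 0.38 and 1.51 ± 0.10. At the other end, transcripts of peroxiredoxin 2 (Prdx2) lay below the median probe, at -2.21 ± 0.42 in WT and -1.96 ± 0.25 in cKO, as did those of cytoplasmic actin (Actb), at -1.44 ± 0.23 and -1.41 ± 0.15. The remaining named genes past the threshold with ratios below the median probe in both genotypes were Rps4l, at -0.62 ± 0.14 and -0.92 ± 0.11, and the glutathione transferase gene Gsta4, at -0.46 ± 0.25 and -0.51 ± 0.21. With normexp the WT ratios of Rps4l and Gsta4 were -0.25 and -0.09 and did not pass, with adjusted p of 0.387 and 0.524 in limma's test. Gsta4 was also no longer past the threshold when WT array 1 (log2 ratio -0.41) or 3 (-0.38), or cKO array 1 (-0.39), 2 (-0.54) or 3 (-0.60), was left out.

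Of 34 named genes with a ratio, 19 differed from the median probe of the array in both genotypes in limma's moderated test (Benjamini-Hochberg adjusted p under 0.05), 15 of them above it and 4 below it. Over all 28363 probes with a ratio, 19004 differed from the median probe in WT, 9408 above and 9596 below it, a near-even split that the centring on the median sets. In cKO 16515 probes differed, 8077 above and 8438 below the median probe. Both genotypes called 14605 of these probes, 7081 above the median probe in both, 7468 below it in both, and 56 in opposite directions. Across probes, which are not independent replicates, the mean ratios of WT and cKO correlated at r = 0.93. Because IP was labelled with Cy5 on every array, a dye effect of a probe cannot be separated from its recovery by the antibody.

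The central question was whether the m6A ratio of a transcript differed between cKO and WT kidneys. The named gene with the largest loss was Pex11a, which takes part in the division of peroxisomes. Its log2 ratio was 1.77 ± 0.07 (SD, n = 3) in WT and 0.68 ± 0.36 in cKO, a difference of -1.09 ± 0.25 (SE) or 2.13-fold, with all 3 cKO values under all 3 WT values. Over all probes its adjusted p was 0.148 in limma's test, so it did not pass the threshold. Among the 17780 probes well above background in both channels on all 6 arrays, it passed, with a difference of -1.21 ± 0.23 and an adjusted p of 0.0413. With the slide as a block no probe passed under that filter, and within slide 2 the Pex11a difference under the main filter was -1.15 with an adjusted p of 0.192. The larger part of the Pex11a difference lay in the supernatant, where its signal differed by 1.04 ± 0.34 (log2, adjusted p = 0.319), while the IP signal differed by -0.12 ± 0.29 (adjusted p = 0.896).

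The other members of the fixed list of fatty acid oxidation and peroxisome genes that had named probes were Ppara, Cpt1a and Acaa2, 3 genes that did not pass the test in the ratio. The ratio of Ppara differed by -0.59 ± 0.32 with an adjusted p of 0.379. The ratio of Cpt1a, the carnitine palmitoyltransferase that brings fatty acids into mitochondria, differed by -0.30 ± 0.34 with an adjusted p of 0.676. That of Acaa2, a mitochondrial thiolase of the same pathway, differed by -0.16 ± 0.22 with an adjusted p of 0.725 in limma's test. Without 1 array the ratio difference ranged from -0.79 to -0.24 for Ppara, from -0.46 to 0.01 for Cpt1a and from -0.24 to -0.07 for Acaa2. Within slide 2, which holds 1 WT array, the ratios of Ppara, Cpt1a and Acaa2 differed by -1.29, -0.92 and -0.30, and none passed. None of the 4 list members passed in total signal, where Pex11a differed by 0.23 ± 0.28, Ppara by -0.18 ± 0.26, Cpt1a by -0.50 ± 0.26 and Acaa2 by -0.51 ± 0.23. Within slide 2, the total signal of Pex11a, Ppara, Cpt1a and Acaa2 differed by 0.76, 0.24, 0.05 and -0.01.

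**Figure D1:**
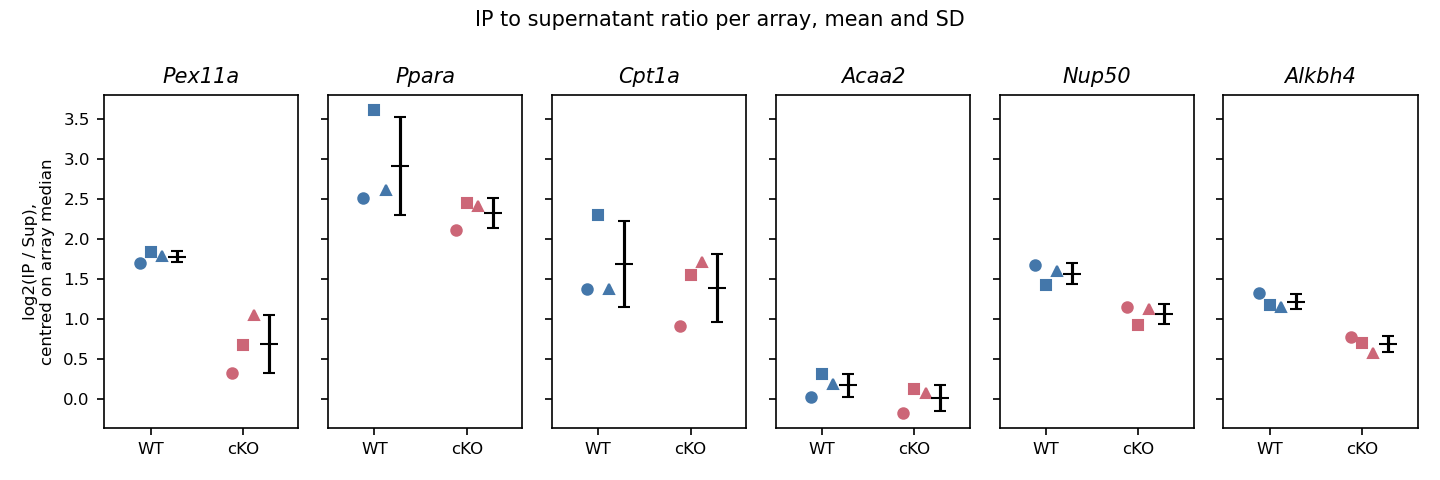
Log2 ratio of IP to supernatant, centred on the median of each array, for 6 named genes; each symbol is 1 array (circle, square and triangle for replicates 1, 2 and 3), and the black bars give the mean and SD of 3 arrays. The 3 cKO values of Pex11a, Nup50 and Alkbh4 lie under the 3 WT values, whereas those of Cpt1a and Acaa2 overlap with WT.

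Further named genes with lower ratios in cKO were the olfactory receptor gene Olfr1307, with -0.87 ± 0.29, the plasma cell chaperone gene Mzb1, with -0.66 ± 0.28, Carhsp1, which encodes an RNA-binding protein, with -0.60 ± 0.24, and Alkbh4, a member of the AlkB family of dioxygenases, with -0.53 ± 0.21. With normexp, loess and Aquantile the differences of these 4 in the m6A ratio were -0.11, -0.05, -0.48 and -0.13, and Olfr1307 and Mzb1 were well above background in the supernatant on 1 of 3 WT arrays. Higher ratios were measured for the caveolin gene Cav2, with 1.00 ± 0.57, the cell cycle regulator E2f1, with 0.69 ± 0.31, Gamt, an enzyme of creatine synthesis, with 0.61 ± 0.25, and Olfr166, with 0.23 ± 0.20. With normexp, loess and Aquantile these were 0.55, 0.11, 0.35 and 0.10. Without 1 array the difference ranged from 0.38 to 1.45 for Cav2 and from 0.40 to 0.87 for E2f1. For Olfr1307 it ranged from -1.04 to -0.57 and for Mzb1 from -0.81 to -0.41. E2f1 was well above background in the supernatant on 1 of 3 WT arrays. None of these 8 passed the threshold, and their adjusted p lay between 0.217 for Olfr1307 and 0.590 for Olfr166. Of the 34 named genes, 8 had an unadjusted p under 0.05 in limma's test, 6 with a lower and 2 with a higher ratio in cKO, and 0 passed after adjustment over all probes or over the named genes alone.

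Over all 28363 probes, 1 probe passed the threshold in the m6A ratio. Its identifier is ASMM10EP3A100083387. Its log2 ratio was 3.64 ± 0.14 in WT and 1.13 ± 0.16 in cKO (n = 3), a difference of -2.51 ± 0.22 with an adjusted p of 0.0451 in limma's test. The larger part lay in the supernatant, where its signal was higher in cKO by 1.72 ± 0.24 (adjusted p = 0.0413 in limma's test). In the IP signal it was not called. An unadjusted p under 0.05 was reached by 4770 probes, 2550 with a higher and 2220 with a lower ratio in cKO, while an unadjusted p under 0.001 was reached by 36 with a higher and 181 with a lower ratio. The 3 values of one genotype lay beyond the 3 of the other for 24.3% of the probes. Arrays that differ at random would give 10% on average. Probes are not independent, slide and genotype nearly coincide, and the ratios spread more widely on the WT arrays. The excess over 10% is therefore descriptive. The count depended on the filter and on the normalisation: among probes well above background on all 6 arrays, 179 passed, 163 with a lower and 16 with a higher ratio in cKO. Normexp with loess and Aquantile in place of the processed signals gave 116, 108 lower and 8 higher. With the slide as a block the main filter and the stricter filter both gave 0, and within slide 2 they gave 0 and 2.

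The whole distribution of ratios was narrower in cKO, a measure chosen after the data were seen. Its interquartile range was 1.59, 1.72 and 1.94 log2 units on WT arrays 1, 2 and 3, and 1.30, 1.41 and 1.43 on cKO arrays 1, 2 and 3. The means were 1.75 ± 0.18 and 1.38 ± 0.07 (SD, n = 3), with p = 0.1 in a two-sided exact permutation test, the smallest p that 3 against 3 arrays allow. After normexp with loess and Aquantile the genotypes overlapped, with means of 0.68 and 0.66. Normexp alone, which adds an offset, already narrowed both genotypes, to means of 0.80 and 0.67, without overlap. The overlap therefore cannot separate a dye trend from this narrowing. Without dye normalisation, over probes well above background on all 6 arrays, and after lowess, the lowest WT array stayed above the highest cKO array, by 0.159, 0.112 and 0.152.

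**Figure D2:**
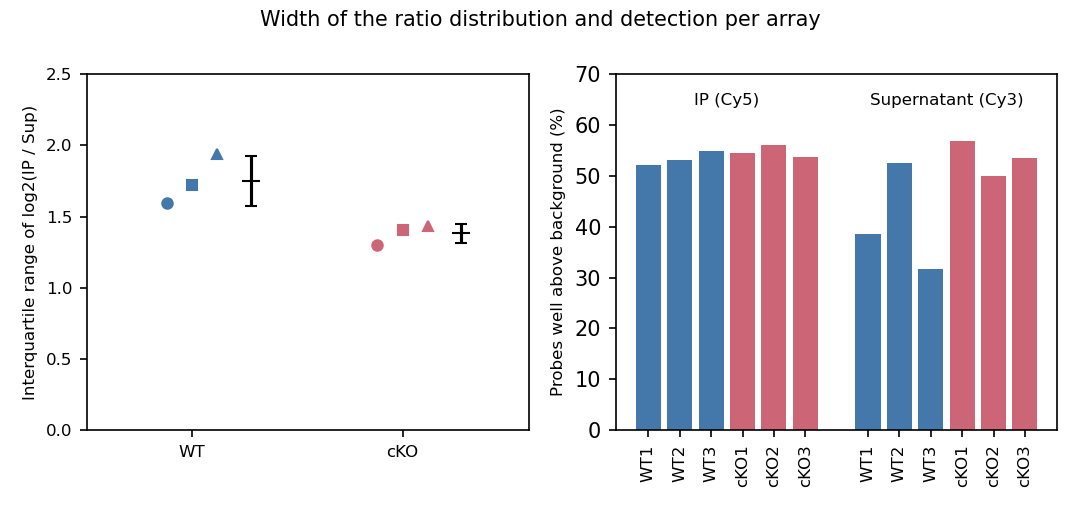
Left, interquartile range of the log2 ratio of IP to supernatant for each array (circle, square and triangle for replicates 1, 2 and 3) with the mean and SD of 3 arrays; right, percent of 60706 probes well above background in each channel of each array. The 3 cKO arrays lie between 1.30 and 1.43 and the 3 WT arrays between 1.59 and 1.94, and the supernatant channel of WT arrays 1 and 3 has the lowest shares, 38.5% and 31.7%.

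A general loss of m6A could also move the overall ratio of IP to supernatant signal. Each fraction was labelled separately, so this ratio need not follow the amount of m6A. Before dye normalisation the median log2 ratio per array was 0.71, -0.11 and 1.58 in WT and -0.06, 0.35 and 0.21 in cKO. The means, 0.73 ± 0.85 and 0.16 ± 0.21 (SD, n = 3), differed by -0.56 with p = 0.4 in a two-sided exact permutation test, which is less than the spread between WT arrays. Within slide 2 the difference had the other sign, 0.28. Of 102 probes whose names mark them as spike-in controls, the 17 well above background in both channels on all 6 arrays served as a reference. Relative to these controls the medians were 0.29, 0.36 and 0.52 in WT and 0.01, 0.21 and 0.22 in cKO. The difference was -0.25 with p = 0.1 in the exact permutation test, and within slide 2 it was -0.21. Over probes well above background on all 6 arrays, a setting chosen after the data were seen, the difference relative to the same controls was -0.12 with p = 0.2 in the exact permutation test, and the genotypes overlapped.

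The total signal of a transcript, the sum of both channels, was compared as an approximation of its abundance. Each channel was first scaled by its own 75th percentile, so the sum does not keep the share of RNA in each fraction. A shift between the fractions could alter it without a change in abundance. The ribosomal protein gene Rps4l differed by 0.96 ± 0.19 log2 units (1.94-fold), from 4.72 ± 0.21 to 5.67 ± 0.16 (SD, n = 3) on a scale where a probe at the 75th percentile of both channels has 1, with an adjusted p of 0.119. H2-M2, a nonclassical class I histocompatibility gene, differed by 0.90 ± 0.19 (1.87-fold), with an adjusted p of 0.136. H2-Q7, another gene of the same family, differed by 0.58 ± 0.21, Nup50, a nuclear pore protein gene, by 0.81 ± 0.26, and the myelin protein gene Mbp by 0.65 ± 0.21. The small-conductance potassium channel gene Kcnn2 differed by -1.40 ± 0.24, from -1.19 ± 0.10 to -2.59 ± 0.44, with an adjusted p of 0.0804, but it was well above background in the supernatant on 0 of 6 arrays and, in cKO, in the IP channel on 1 of 3, so that the size of the difference is uncertain. The hyaluronidase gene Hyal3 differed by -0.77 ± 0.17, with an adjusted p of 0.167. With normexp, loess and Aquantile the total signal differences of Kcnn2, Hyal3, Mbp, Nup50 and Trp53rka were -0.19, -0.21, 0.14, 0.49 and -0.17. Mbp and Trp53rka were well above background in the supernatant on 0 of 3 WT arrays, and Hyal3 on 1 of 3. Smaller differences were measured for Acaa2, for Trp53rka (-0.45 ± 0.18) and for Actb (-0.44 ± 0.21). Rps4l, Trp53rka and both H2 genes have close relatives in the genome, and a probe could take signal from them.

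Of 38 named genes with a total signal, 0 passed the threshold over all probes in limma's test, while 8 had an unadjusted p under 0.05. With the limma p adjusted over the named genes alone, a set taken after the data were seen, 4 passed: Kcnn2 with an adjusted p of 0.0107, Rps4l and H2-M2 each with 0.0135 and Hyal3 with 0.0173. Within slide 2, where 1 WT array cannot separate slide from genotype, the differences were -1.44 for Kcnn2, 1.17 for Rps4l, 1.05 for H2-M2, 1.31 for Nup50, 0.86 for H2-Q7, 0.67 for Mbp, -0.77 for Hyal3, -0.23 for Trp53rka, -0.28 for Actb and -0.01 for Acaa2, and none passed with the slide as a block.

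**Figure D3:**
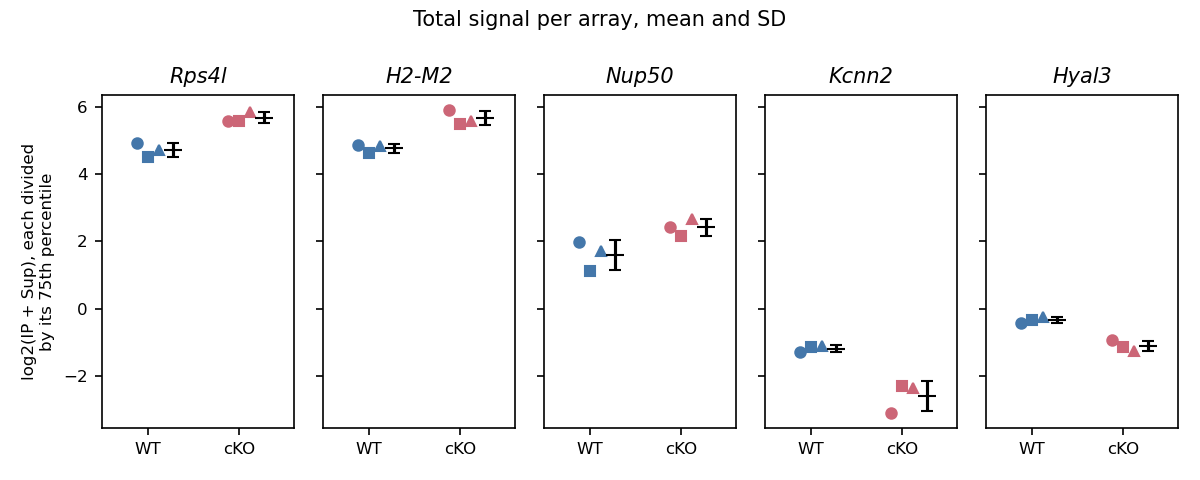
Total signal, log2 of the sum of IP and supernatant signal after each was divided by its 75th percentile on the array, for 5 named genes; each symbol is 1 array (circle, square and triangle for replicates 1, 2 and 3), and the black bars give the mean and SD of 3 arrays. For each gene the 3 WT and the 3 cKO values do not overlap, with Rps4l, H2-M2 and Nup50 higher and Kcnn2 and Hyal3 lower in cKO.

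Among all 36070 probes with a total signal, 68 passed the threshold, 47 higher and 21 lower in cKO, whereas the 3486 probes with an unadjusted p under 0.05 split the other way, 1387 higher and 2099 lower. The largest rises with values on all arrays were those of probes ASMM10EP3A100173013, from 1.49 ± 0.35 to 4.96 ± 0.19 (log2, n = 3), with an adjusted p of 0.00250, and ASMM10EP3A100131049, from -0.09 ± 0.23 to 3.28 ± 0.42, with an adjusted p of 0.00479. The second was not well above background in the supernatant of any WT array. After normexp, loess and Aquantile its cKO supernatant signal was 2.03-fold higher, a measured value rather than a lower bound. With the same processing the total signal differences of the 2 probes were 2.66 and 1.99. The largest fall was that of ASMM10EP3A100191347, from 2.19 ± 0.13 to -1.75 ± 1.35, with an adjusted p of 0.0426, but in cKO this probe was well above background in each channel on 1 of 3 arrays, and with normexp, loess and Aquantile the difference was -1.37. None of these 3 passed with the slide as a block, with adjusted p of 0.0649, 0.0649 and 0.456, and within slide 2 only the first did. The falling probe passed in 5 of 15 alternatives, and of the settings without 1 array only without cKO array 3. The count was 3 with the slide as a block and 3 within slide 2. It was 42, 20 and 6 without WT array 1, 2 or 3 and 4, 18 and 8 without cKO array 1, 2 or 3. With normexp it was 19, 17 of them higher, and with normexp, loess and Aquantile it was 22, 18 of them higher.

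The fractions were also compared separately. In the supernatant, the fraction not bound by the antibody, the named genes with the smallest p were Rps4l, with a log2 difference of 1.09 ± 0.20 (SE), Nup50, with 1.20 ± 0.23, and H2-M2, with 0.92 ± 0.22. These 3 passed in limma's test when adjusted over the 34 named genes alone, which was chosen after the data were seen, with p of 0.0131, 0.0131 and 0.0370, and did not pass over all probes, with adjusted p of 0.0944, 0.104 and 0.183. In the IP fraction Kcnn2 (-1.53 ± 0.31), Hyal3 (-1.02 ± 0.23) and H2-M2 (0.90 ± 0.21) passed in limma's test when adjusted over the 38 named genes alone, each with an adjusted p of 0.0246, and did not pass over all probes, with adjusted p of 0.147, 0.174 and 0.176. With normexp, loess and Aquantile the differences were -0.26 for Kcnn2 and -0.26 for Hyal3 in the IP signal and 0.52 for Nup50 in the supernatant signal, and Kcnn2 was well above background in the IP channel on 1 of 3 cKO arrays. An unadjusted p under 0.05 was reached by 7 named genes in the supernatant and 9 in the IP fraction, and 0 passed over all probes. H2-M2 differed by a similar amount in both fractions, and its ratio differed by 0.02 ± 0.22.

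Over all probes, 68 of 31173 passed in the supernatant, 62 higher and 6 lower in cKO, and 28 of the 62 were not well above background in any WT supernatant. With probes well above background on all 6 arrays alone, 69 passed, 49 higher and 20 lower. In the IP fraction 35 of 33517 passed, 23 higher and 12 lower, and 47 with that filter, 24 higher and 23 lower. The fractions shared 12 calls, all in the same direction, but they come from the same kidneys and spots, so this is descriptive. With the slide as a block 1 supernatant and 0 IP calls were left, and within slide 2 there were 159 and 5, 147 and 5 of them higher. At an unadjusted p under 0.05 there were 3209 supernatant probes, 2212 higher and 997 lower, and 3963 IP probes, 1588 higher and 2375 lower. In the total signal 29 of the IP calls and 35 of the supernatant calls were called too, and these values share spots as well.

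Whether differences in m6A ratio and in total signal fell on the same probes could not be judged at the threshold, since the ratio had 1 call. With the 68 total signal calls 0 were shared, where the product of the shares gives 0.00190. At an unadjusted p under 0.05 with at least a 1.5-fold change in both, 273 probes were shared, 99 with a lower ratio and higher total signal, 101 with both lower, 38 with both higher, and 35 with a higher ratio and lower total signal. The product of the shares is 213, but both values come from the same spots, so this count is descriptive. Across 28363 probes, which are not independent replicates, the changes in ratio and in total signal correlated at r = 0.03.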

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

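The tests within slide 2 and the other splits of the arrays for the counts were chosen after the result was seen, while the strict filter and the slide as a block were planned. The effect of genotype on the IP to supernatant ratio was larger than the spread between arrays for probe ASMM10EP3A100083387, whose log2 ratio in cKO differed from that in WT by -2.51. Within slide 2 the difference was -2.62, and with the slide as a block its adjusted p was 0.212. In 10 splits of the 6 arrays into 3 and 3, which are too few for a share under 0.05, the labelled split gave this 1 call and the highest of the others gave 0.

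The ratio calls were mostly lower in cKO among probes well above background on all 6 arrays, 163 of 179. The highest of the other splits gave 0 calls, and 1 of 10 splits gave as many as 179, too few splits for a share under 0.05. A difference between the slides could account for the direction, since 2 of the 3 WT arrays lay on slide 1. Within slide 2, 72.1% of the 240 probes with an unadjusted p under 0.001 were lower in cKO, which does not settle it with 1 WT array there, so slide and genotype cannot be told apart for these probes. Of the 163 lower calls, 156 had a higher supernatant signal in cKO (median log2 change 0.84) and 145 a lower IP signal (median -0.44). Among all 17780 probes of the filter the supernatant signal was higher for 6621 and the IP signal lower for 8982. The calls were chosen by the ratio of these same signals, so both directions follow in part from the choice. The supernatant is the channel that was dim on WT arrays 1 and 3. The mean ratio was nearer to 0 in cKO for 149 of the 163 lower and 15 of the 16 higher calls. Over all 17780 probes of the filter this held for 12091. A lower m6A level in the knockout stays open as the biological explanation, untested.

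Of 68 supernatant calls, 62 were higher in cKO, and with the strict filter, which leaves out probes dim on any array, 49 of 69. The supernatant channel was dim on WT arrays 1 and 3, which could raise such calls. Within slide 2, without those arrays, 92.5% of 159 calls were higher in cKO. The probes of that fit, 31173 as in the main fit, were still chosen by the filter over the arrays of both slides. A probe well above background in the WT supernatant alone had to be so on WT arrays 1 and 3 too. Those arrays can therefore still shape the direction through the filter. The fit also rests on 1 WT array, so the explanation cannot be told apart from an effect of genotype. The count of 68 was reached in 1 of 10 splits, with 0 as the highest of the others. The 68 total signal calls and 35 IP calls likewise had 0 as the highest of the others, in 1 of 10 splits each, which are too few for a share under 0.05. For the overlap of ratio and total signal calls, 0 in the labelled split, all 10 splits gave 0. For IP against supernatant, exchanging the channels of single arrays gave at most 0 calls against 19004 in WT and 16515 in cKO, in 1 of 4 exchanges each, also too few.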

How the results depend on the processing

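The within-slide settings and the spike-in setting with the strict filter were chosen after the data were seen. For the m6A ratio the count of 1 became 0 with normexp, with no filter, with trend and robust variance, with the slide as a block and within slide 2, 3 without dye normalisation, 116 with normexp, loess and Aquantile, 179 with probes well above background on all 6 arrays, and 4369 at an unadjusted p under 0.05 with 1.5-fold. Without 1 array it was 0 to 2, with 2 without WT array 1 and 0 without any other. For the total signal, 68 became 19 with normexp, 22 with normexp, loess and Aquantile, 159 with trend and robust variance, 3 with the slide as a block, 3 within slide 2 and 2083 at the unadjusted threshold. It was 42, 20 and 6 without WT array 1, 2 or 3 and 4, 18 and 8 without cKO array 1, 2 or 3. For the IP signal, 35 became 3 with normexp, 5 (4 higher) with normexp, loess and Aquantile, 17 without dye normalisation, 4 with no filter, 72 with trend and robust variance, 0 with the slide as a block, 5 within slide 2 and 3373 at the unadjusted threshold, and 0 to 12 without 1 array (6, 12 and 4 without WT array 1, 2 or 3 and 2, 0 and 0 without cKO array 1, 2 or 3). For the supernatant signal, 68 became 37 with normexp, 27 with normexp, loess and Aquantile, 41 without dye normalisation, 16 with no filter, 160 with trend and robust variance, 1 with the slide as a block, 159 within slide 2 and 2681 at the unadjusted threshold, and 0 to 100 without 1 array (30, 7 and 100 without WT array 1, 2 or 3 and 0, 2 and 2 without cKO array 1, 2 or 3). The fits within slide 2 and without an array use fewer samples. With the slide as a block the genotype difference rests on WT array 2 alone, since slide 1 holds only WT arrays. Its estimate is the one within slide 2, so these are not separate checks. For the other settings the cause was not tested. Where 1 WT array remains, its variation is assumed to be that of the cKO arrays.

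Counts of IP against supernatant stayed within 1.5 times under every setting run, from 17064 to 17810 in WT and from 12181 to 14188 in cKO without 1 array. The overlap of ratio and total signal calls was 0 with normexp and 273 at the unadjusted threshold. The difference of median log2 ratios, -0.56, ranged from -0.98 to -0.13 without 1 array, and changed sign to 0.0273 with median signals without background subtraction and to 0.28 within slide 2; the cause was not tested.

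With the replicate number as a block the counts were 0 for the ratio, 28 for the total signal, 11 for the IP signal and 0 for the supernatant signal. The numbers name different animals in WT and cKO, so a shared number does not by itself link a WT array to a cKO array. The pairing found no uniform backing: deviations of arrays with the same number correlated at 0.33, 0.27 and 0.08 for the ratio, 0.10, 0.26 and 0.07 for the IP signal, -0.09, 0.24 and -0.03 for the total signal and -0.11, 0.17 and -0.10 for the supernatant signal. Arrays that correlated best with their own number were 6 of 6 for the ratio, 5 for the IP signal, 2 for the total signal and 2 for the supernatant signal.

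Changes of 44 named gene values kept their direction and their side of the threshold in 680 of 698 settings. In 3 they passed: Pex11a in the ratio with the strict filter, Rps4l in the supernatant with normexp, loess and Aquantile (adjusted p = 0.00763) and Nup50 in the supernatant with trend and robust variance (adjusted p = 0.0353). In 15 they changed sign, none of them past the threshold. In the ratio these were Mzb1 with normexp (0.00522) and Cpt1a without WT array 2 (-0.458 to 0.0148 without 1 array). In the total signal they were Cpt1a (0.0528) and Ppara (0.244), each with the slide as a block and within slide 2, Ppara without cKO array 2 (-0.397 to 0.0215 without 1 array) and Pex11a without WT array 2 (-0.0364 to 0.455 without 1 array). In the IP signal they were Ppara (0.0913) and Pex11a (0.411), each with the slide as a block and within slide 2. The others in the IP signal were Pex11a with normexp (0.0341), without WT array 1 and without cKO array 2 (-0.388 to 0.0964 without 1 array). Where both are named, the slide as a block and within slide 2 gave the same estimate, counted under both. Of 138 settings for single genes in IP against supernatant, 128 kept the call, and the 10 that lost it were 9 for Gsta4 and 1 for Rps4l. The tests of Mettl3 and of gene lists were not run, for want of named probes. Dim supernatant signal on WT arrays 1 and 3 limits what can be measured there.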

Other observations

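All tests in this part were chosen after the result was seen. Probes with the prefix ASMM10SM1, 1531 in the ratio, had lower ratios than the rest, and more so in WT. Their median log2 ratio was -0.79, -0.84 and -0.88 on WT arrays 1, 2 and 3 and -0.42, -0.59 and -0.50 on cKO arrays 1, 2 and 3, with p = 0.1 in an exact permutation test, the smallest it can give. What this prefix stands for is not given in the sources used here. Of named genes, Gapdh, read from its 3′ control probe, had a log2 ratio relative to the array median of -1.49 ± 0.11 in WT and -0.97 ± 0.16 in cKO (SD, n = 3), and Pgk1 had 0.12 ± 0.10 and 0.11 ± 0.29.

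The distribution of the IP to supernatant ratio was narrower on the cKO arrays, and more probes lay nearer to the array median there. Of 17780 probes well above background on all 6 arrays, 12091 had a mean ratio nearer to 0 in cKO than in WT. Independent measurement noise on the WT arrays would widen the distribution without raising the covariance between arrays. The lowest covariance between WT arrays exceeded the highest between cKO arrays by 0.240, which argues against independent noise alone. The pairs share arrays, so the SD of either set (0.176 and 0.0939) does not measure the error of this gap. Correlations between arrays were 0.885 to 0.892 in WT and 0.887 to 0.944 in cKO, so more noise on the WT arrays is not excluded. Noise shared by WT arrays would raise the covariance and was not tested. A dye bias that depends on signal strength stays open. After lowess of the ratio on mean signal the lowest WT array was still 0.152 above the highest cKO array. Normexp with loess and Aquantile brought the genotypes to overlap, but it changed more than the dye trend. Normexp alone cut the difference of means from -0.37 to -0.13. With loess and Aquantile added, WT array 2 stayed at 0.80, above the highest cKO array at 0.67. WT arrays 1 and 3 were then at 0.63 and 0.62, under all cKO arrays. A difference between the slides also stays open, since WT array 2 lay 0.290 above the highest cKO array on its own slide but is a single array. A weaker contrast between methylated and unmethylated transcripts in the knockout may be the biological explanation, and it remains a hypothesis that was not tested here.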
